A study of Musca domestica with 16 samples.

How the data were processed

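Messenger RNA of unmated house flies 4 to 6 days old, kept at 25 °C, was sequenced from male heads, testes, female heads and ovaries of strains CS and CSaY, per the labels' protocols. The 16 libraries comprise 3 per strain for male heads, 3 per strain for testes, and 1 per strain for female heads and for ovaries. RNA was extracted with TRIzol and RNeasy columns and polyA-selected TruSeq libraries were made, per the labels' protocols. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.8b, Bowtie2 2.1.0.0 and Cufflinks 2.2.1, and their roles and the genome build are not given in the sources used here.

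The FPKM values are group values made by the authors before deposit, per the file headers 1 value for each strain in each tissue of each sex and 4 further columns that pool the strains. The score of each comparison is the test statistic in the authors' deposited table, and it entered no computation here. The q value of each of the 6 comparisons was computed by the authors and is used as deposited, and how it was adjusted is not given in the sources used here. A gene with no q was not tested by the authors. Each female strain column holds 1 library. Values of single male libraries and read counts were not used here, so read depth and the spread between male libraries cannot be given. For low values, 1 read in the CSaY female head library was worth 1.21 times as much FPKM as 1 read in the CS library, and the same ratio was 0.983 for the ovary libraries. The pooled columns differ in scale from the columns they pool (median ratio to their mean 1.19 for female heads, 0.875 for male heads, 1.27 for ovaries and 1.01 for testes), so folds are taken within 1 kind of column. Percentages of the testis level divide by the pooled column and carry these scale differences. Percentages of the female head level divide by the lower of the strain columns of CS and CSaY female heads.

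A gene was called different when the authors' q lay below 0.05, and no test of single genes was added. Log2 fold changes were computed from FPKM + 1 and are given as Y^M minus III^M (CSaY minus CS in females), male minus female, and testis minus ovary. Folds are ratios of the FPKM values themselves, and none is given against a value of 0. Gene names come from a table of assembly GCF_030504385.1, used for names only, in which 12168 of 14631 gene IDs were found (83.2%) and 52 had an informative symbol. Positions are those of the authors' deposited table, whose assembly is not named in the sources used here. Several genes share 1 locus at 764 loci (1732 genes), and how reads were divided there, or between related copies, is not given in the sources used here.

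The comparisons, thresholds, 23 gene lists and the rule for naming genes were chosen before the data were examined. The rule names, among called genes with at least 5 FPKM in the higher group, the 10 genes with a symbol and the 2 of any kind with the largest change in each direction of a strain comparison (5 and 1 in a sex comparison), up to 4 called members of each list, and Sxl. Other genes with a symbol in the text, such as TCTP, the chaperonin genes and genes that were not called, and the ortholog groups, were chosen after their values were seen. Of the 23 lists 10 had a member with a matching name and 13 had none, and the cytochrome P450 list alone had at least 5 tested members. Lists, ortholog groups, chromosomes and overlaps between comparisons were tested with two-sided Fisher's exact tests against the other tested genes, with Benjamini-Hochberg adjustment. Each gene was put on a chromosome by its scaffold in the authors' deposited table (11231 genes). A second assignment in that table, by ortholog, agrees in 6253 of the 6752 genes that have both (92.6%). Chromosome labels were permuted over scaffolds 10000 times (2000 for rho), because neighbouring genes are not independent. In 40 simulated sets with an odds ratio of 2.5 the median recovered was 2.51 for testes (8730 genes) and 2.54 for male heads (8030 genes). In 40 simulated sets with calls clustered on scaffolds and no effect of chromosome, Fisher's test gave p below 0.05 in 12 and 10 sets and the permutation in 1 and 1.

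Alternatives tried were q below 0.01, a minimum of 2-fold, a pseudocount of 0.1, median-centred fold changes, a mean FPKM of at least 1 or 10 and another background of genes. After the data were seen, the ortholog-based chromosome, single-copy orthologs alone, 10 strata of mean FPKM and the removal of chromosome III were added, and the 0.01 and 2-fold settings were also run on the comparison of tissues. The scaffold permutations of the X chromosome, of call directions, of shared directions and of the sex comparison of heads, and the strain columns in place of the pooled columns, were also added then. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.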

Results

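Sex in the house fly, Musca domestica, is set by a male determiner that can sit on different chromosomes. The libraries come from 2 strains. In strain CS the determiner lies on chromosome III, so its males are III^M males, and in strain CSaY it lies on the Y chromosome, so its males are Y^M males. Messenger RNA was sequenced from heads and gonads of unmated adults, 4 to 6 days old, in 16 libraries. Each male group (III^M heads, Y^M heads, III^M testes, Y^M testes) had 3 libraries. Female heads and ovaries had 1 library per strain in each tissue. The authors' deposited table holds 1 FPKM value per group for 14631 genes, with a q value for each of 6 comparisons, and a gene is called different here when that q lies below 0.05. Values of single male libraries were not used here, so no spread between male libraries can be given. A symbol was matched for 52 genes, and the named results below rest on those.

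Several serpins, the yolk protein gene yp3 and the antimicrobial gene diptericin were lower in the heads of Y^M males than in those of III^M males. The gene yp3, which encodes a yolk protein taken up by the growing egg, stood at 66.0 FPKM in III^M male heads and 3.82 FPKM in Y^M male heads in the authors' deposited table, a 17.3-fold difference. Diptericin, an antimicrobial peptide against Gram-negative bacteria, was 6.19-fold lower in Y^M heads (297.7 against 48.1 FPKM). Defensin-1, an antimicrobial peptide of another family, moved the other way and was 2.48-fold higher in Y^M heads (471.9 against 1171 FPKM), while another of the 5 genes in its ortholog group was 1.68-fold lower. The call for each of the 3 genes had q = 0.00138 in the authors' deposited table, the smallest q of this comparison, which 343 genes shared.

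Among the 9441 genes tested between the male heads, 873 were called, 320 higher and 553 lower in Y^M males. Of the 45 tested genes with a symbol, 1 was higher, 7 were lower and 37 were not called. Serpins are inhibitors of serine proteases that hold immune and clotting cascades in check. Of the 9 tested members of the ortholog group that holds Spn2, SPN9 and SPN13, a group chosen after its values were seen, 6 were lower in Y^M heads, 0 were higher and 3 were not called. The share of 66.7% compares with 9.19% of the other tested genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.00127 over 63 group tests). Spn2 fell from 9.20 to 2.88 FPKM, SPN13 from 13.8 to 4.70 FPKM and SPN9 from 41.6 to 24.2 FPKM. SPN9 and SPN13 lie on scaffold NW_004764673 (positions 387257 to 397659 and 443890 to 445376), and Spn2 lies on scaffold NW_004764543 of chromosome V (positions 565265 to 574724). The called members without a symbol lie on the scaffold of Spn2 as well, between positions 538157 and 623196. Fisher's test counts such neighbours as independent, so its p can be too small. How reads were divided among such related copies is not given in the sources used here, so the level of each copy is uncertain. Ornithine decarboxylase (ODC), the first enzyme of polyamine synthesis, fell 2.22-fold from 45.6 to 20.5 FPKM. A glutathione S-transferase (GST), an enzyme of detoxification, fell 1.76-fold from 2572 to 1463 FPKM. None of the 5 tested cytochrome P450 genes with a symbol was called in this comparison. Sxl, which controls sex in Drosophila, stood at 30.3 FPKM in III^M and 31.6 FPKM in Y^M heads (q = 0.923 in the authors' deposited table).

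The largest falls in Y^M heads belonged to LOC101888455, at 31.9 FPKM in III^M heads and listed at 0 in Y^M heads, and LOC101900280, which fell from 127.4 to 3.25 FPKM. LOC101888455 is a gene of 283 bases whose testis level was 29693 FPKM, so its level in III^M heads was 0.107% of that in testis. The largest rises belonged to LOC101898334 and LOC101896119, listed at 0 in III^M heads and at 11.2 and 8.27 FPKM in Y^M heads. A value listed at 0 can be a failed estimate in such a table, and no fold is given against it. In the single female head libraries diptericin was not called and stood at 818.8 FPKM in the CS and 1.23 FPKM in the CSaY female head library (q = 0.998 in the authors' deposited table).

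**Figure D1:**
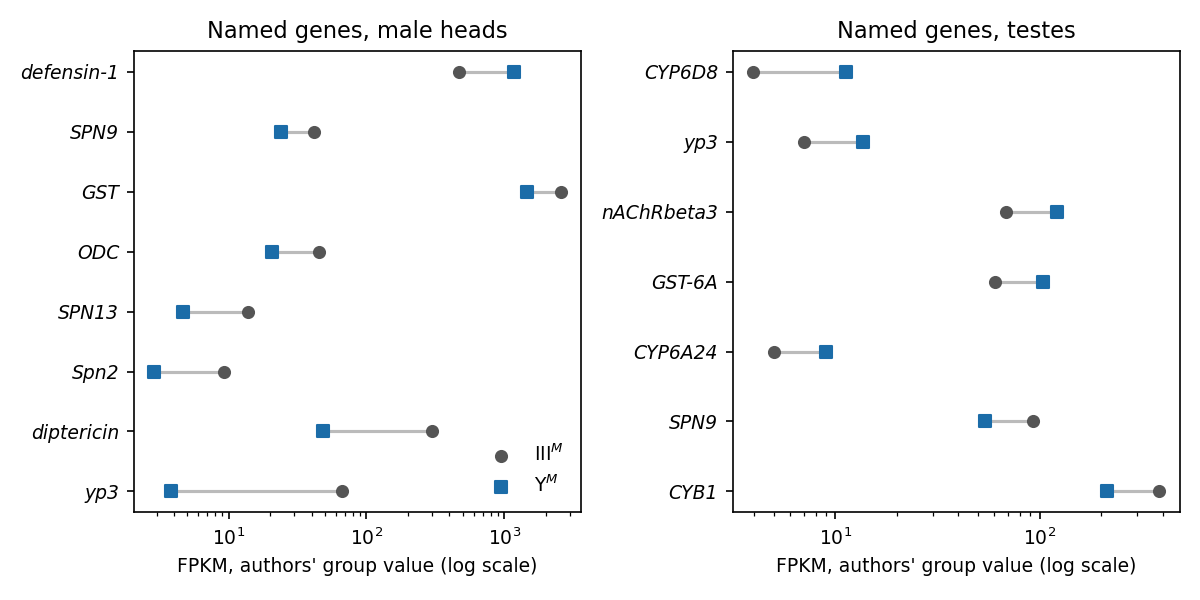
FPKM of genes with a symbol called between Y^M (squares) and III^M (circles) males, in heads (left) and testes (right), on log axes. Only genes with at least 5 FPKM in the higher group are drawn, so bcd, called in testes, is left out. Values are the authors' group values over 3 libraries each, with no error bars because values of single libraries were not used. In heads yp3 stands at 66.0 FPKM in III^M and 3.82 FPKM in Y^M males, and in testes at 7.05 and 13.6 FPKM.

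Single genes of detoxification families moved in both directions between Y^M and III^M testes. CYP6D8, a cytochrome P450, rose 2.85-fold from 3.94 to 11.3 FPKM, CYP6A24, another P450, rose 1.81-fold from 4.98 to 9.03 FPKM, and the glutathione S-transferase GST-6A rose 1.73-fold from 60.2 to 104.1 FPKM. In the same families 2 other members of the ortholog group of GST-6A were 3.49-fold and 1.69-fold lower in Y^M testes, and 2 members of the P450 groups were 2.90-fold and 1.71-fold lower. The nicotinic acetylcholine receptor subunit nAChRbeta3 rose 1.78-fold from 68.7 to 122.1 FPKM. Yp3 rose 1.93-fold, from 7.05 to 13.6 FPKM, opposite in direction to the heads. Of the 6 tested members of its ortholog group 1 was higher, 1 was lower and 4 were not called. The lower member, LOC101889813 on the scaffold of yp3, stood at 3.21 FPKM in III^M testes and was listed at 0 in Y^M testes. CYB1 fell 1.80-fold from 385.2 to 214.2 FPKM and SPN9 fell 1.73-fold from 93.1 to 53.7 FPKM.

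In all, 1338 of 10275 genes tested in testes were called, 782 higher and 556 lower in Y^M males. Of the 44 tested genes with a symbol, 5 were higher, 3 were lower and 36 were not called. The P450 list fixed before the data were examined had 5 tested members, of which 2 were higher and 3 were not called (Fisher's exact test, adjusted p = 0.324 over 5 list tests). The P450 ortholog groups had 3 genes higher and 2 lower of 35 tested, and the group of GST-6A had 1 higher and 2 lower of 5 (Fisher's exact test, adjusted p = 0.121 for the latter). The serpin group showed 1 member higher and 2 lower of 10 tested (Fisher's exact test, adjusted p = 0.532). Diptericin and defensin-1 did not pass the test here, with diptericin at 2.08 FPKM in III^M and 4.18 FPKM in Y^M testes (q = 0.352 in the authors' deposited table) and defensin-1 with q = 0.973, while a neighbour of defensin-1 in its ortholog group was 2.21-fold higher in Y^M testes (q = 0.0167 in the authors' deposited table). Bcd, which patterns the front of the embryo in Drosophila, fell 3.40-fold to 0.577 FPKM (q = 0.0132 in the authors' deposited table). The largest rises belonged to LOC101889108, from 2.47 to 71.9 FPKM, and LOC101895910 on chromosome III, from 14.2 to 164.4 FPKM. LOC101895397 and LOC101894393 stood at 166.9 and 74.2 FPKM in III^M testes and were listed at 0 in Y^M testes.

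The strains differ in which chromosome carries the male determiner, so the chromosome of each called gene was compared. Genes on chromosome III were called in excess in both male tissues. In testes 378 of 1602 tested genes on chromosome III differed between the strains (23.6%, Wilson 95% interval 21.6 to 25.7%), with shares of 9.17 to 9.81% on chromosomes I, II, IV and V. In male heads the share on chromosome III was 16.0% (234 of 1462, interval 14.2 to 18.0%), with 5.44 to 7.23% on those 4 chromosomes. The odds ratio of chromosome III against the other chromosomes was 2.92 in testes (95% interval 2.54 to 3.36, adjusted p = 2.6e-46) and 2.62 in male heads (interval 2.21 to 3.11, adjusted p = 1.53e-25) by Fisher's exact test with adjustment over 6 chromosomes. Genes on one scaffold are not independent, and when chromosome labels were permuted over whole scaffolds the excess in the called share was 14.04 percentage points in testes and 9.23 in male heads, with p = 0.0001 for both, the smallest that 10000 permutations can give. Chromosome III held diptericin, yp3 and nAChRbeta3 among the named calls.

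The direction of the calls differed by chromosome in heads. On chromosome III 137 of the 234 called genes were higher in Y^M heads (58.5%), against 26.5% of the called genes on all other chromosomes (scaffold permutation p = 0.0001, the smallest possible). On chromosome V 25 of 121 called genes were higher (20.7%), against 41.2% on all other chromosomes, chromosome III included (scaffold permutation p = 0.0013). The shares on chromosomes I, II and IV were 23.7%, 30.1% and 30.0%, and chromosome V was not tested against those alone. In testes 226 of the 378 called genes on chromosome III were higher (59.8%), against 57.1% elsewhere (scaffold permutation p = 0.505). Over all tested genes, called or not, chromosome III was shifted toward Y^M in both tissues, with a median log2 fold change above that of the other chromosomes by 0.07 in testes and 0.09 in male heads (scaffold permutation p = 0.0001 for both). On the X chromosome, a small chromosome in this table, 12 of 34 tested genes differed in testes (35.3%, interval 21.5 to 52.1%, scaffold permutation p = 0.0105, 6 scaffolds). Of these 12 genes 8 were higher in Y^M testes. With the chromosome taken from each gene's ortholog, 4 of 28 tested genes on X were called and the odds ratio was 1.46 (Fisher's exact test, p = 0.524). That assignment also covers a different set of genes, so what weakened the excess was not tested. Among single-copy orthologs placed by scaffold the odds ratio was 3.81 (Fisher's exact test, p = 0.0726).

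Between the single female libraries no such excess was seen. Of the genes tested on chromosome III, 9 of 1456 were called between the female head libraries (0.618%) and 5 of 1265 between the ovary libraries (0.395%). In testes the median absolute log2 fold change of FPKM + 1 was 0.32 on chromosome III and 0.21 elsewhere, an excess of 0.11, and in ovaries the excess was 0.01. The excess in testes minus that in ovaries was 0.09 over the genes tested in both (scaffold permutation p = 0.0001). The same difference between male and female heads was 0.06 (scaffold permutation p = 0.0001, again the smallest possible). The female comparisons set 1 library against 1 library, so the authors' test there compares those libraries, not the strains, and with 73 and 28 calls in all an excess in females is not excluded.

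**Figure D2:**
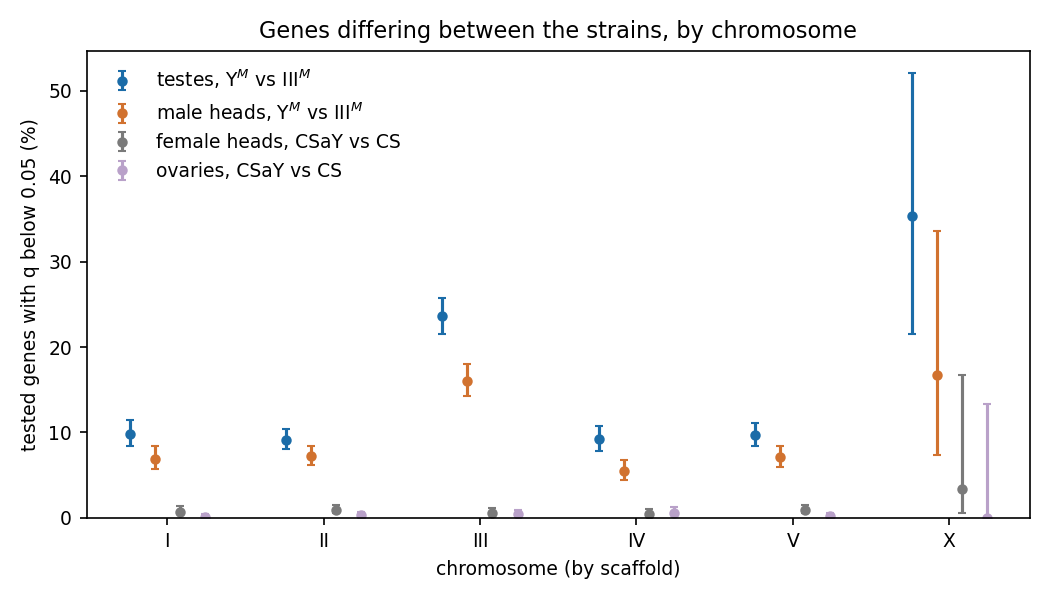
Share of the tested genes with q below 0.05 (percent, y axis) on each chromosome (x axis, assigned by scaffold) in the 4 strain comparisons, with Wilson 95% intervals as bars. On chromosome III the share is 23.6% in testes and 16.0% in male heads, above chromosomes I, II, IV and V, and it is 0.618% in female heads and 0.395% in ovaries.

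Most genes that differed between the strains in both male tissues did so in the same direction. Among the 8314 genes tested in both tissues 176 were called in both, where independent lists would share 80.3. Of these 128 moved the same way (72.7%), with 56 higher and 72 lower in Y^M males, and 48 moved in opposite ways. SPN9 was lower in Y^M males in both tissues, and yp3 was lower in heads and higher in testes. On chromosome III 58 of 72 shared genes moved the same way, and on the other chromosomes 41 of 66 did (scaffold permutation p = 0.0272). Across genes, which are not independent replicates, Spearman's rho between the fold changes of testis and head was 0.209 on chromosome III and close to 0 elsewhere. The difference of 0.210 exceeded all 2000 permutations over scaffolds (p = 0.0005, the smallest these can give). The authors' deposited table has no test of strain by tissue, so the difference for a single gene was not tested.

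Heads of females carried more transcript of cytochrome P450 genes, of yp3 and of the sodium channel gene para-like than heads of males. Yp3 stood at 1008 FPKM in female and 29.3 FPKM in male heads, a 34.4-fold difference. CYP6D8 was 7.91-fold higher in female heads (3450 against 435.9 FPKM), CYP6A24 3.24-fold, CYP6D3 3.25-fold and CYP6G4 2.42-fold. Para-like, a voltage-gated sodium channel gene that underlies the action potential, was 4.30-fold higher in female heads (65.0 against 15.1 FPKM). ODC was 3.95-fold, diptericin 3.09-fold, GST-6A 2.30-fold and TCTP 2.13-fold higher. Some of these values rest on 1 of the 2 female libraries. Diptericin stood at 818.8 FPKM in the CS but 1.23 FPKM in the CSaY female library, below both male groups (297.7 and 48.1 FPKM). CYP6D3 stood at 94.6 and 29.9 FPKM in these libraries, beside 31.2 FPKM in III^M heads. ODC stood at 47.7 and 152.0 FPKM, beside 45.6 FPKM in III^M heads, and yp3 at 346.7 and 1328 FPKM, above both male groups. In the authors' deposited table q was at most 0.00563 for each of these genes. These folds come from the pooled columns, whose scale puts females 1.36 times higher against males than the strain columns do. The means of the strain columns give 23.97-fold for yp3, 5.39-fold for CYP6D8, 2.71-fold for para-like, 2.13-fold for CYP6A24, 1.91-fold for CYP6G4, 1.66-fold for GST-6A and 1.57-fold for TCTP.

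Heads of both strains were pooled here, 6 male and 2 female libraries. The authors' test called 1292 of 9679 genes, 1087 higher in females and 205 higher in males. Both female libraries lay above both male groups in 858 of the 1087 genes (78.9%), and below both in 191 of the 205 (93.2%). The median log2 ratio of male to female over the tested genes was -0.12 in the pooled and 0.36 in the strain columns. Of the called genes 774 were at least 2-fold higher in females and 117 in males by the pooled columns, and 462 and 188 by the strain columns, so the size of the imbalance depends on the scale. The direction differed between both kinds of columns in 10 called genes. In the fixed P450 list 4 of 5 tested genes were higher in female heads, 0 in male heads (Fisher's exact test, odds ratio 26.04, adjusted p = 0.00706 over 5 list tests). In the ortholog groups that hold these P450s 17 of 41 tested genes were higher in female heads, 0 were higher in male heads and 24 were not called, a share of 41.5% against 13.2% of the other genes (Fisher's exact test, adjusted p = 0.000492). In the group of GST-6A 4 of 5 genes were higher in female heads (Fisher's exact test, adjusted p = 0.0297). Several members of these groups are neighbours on a scaffold, and Fisher's test counts them as independent, so these p values can be too small. The only symbol gene called higher in male heads was SPN13, at 7.97 against 3.21 FPKM (q = 0.0495 in the authors' deposited table). Sxl stood at 21.6 FPKM in female and 27.6 FPKM in male heads (q = 0.503 in the authors' deposited table). LOC101892639 had the largest difference, at 43187 FPKM in female and 38.8 FPKM in male heads, and LOC101889469 stood at 546.6 FPKM in male heads and was listed at 0 in female heads. Chromosome II was called less often than the rest (10.99% against 13.7%, scaffold permutation p = 0.0066) and chromosome III slightly more often (15.03% against 12.57%, p = 0.0204 by the same permutation).

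Testis and ovary differed in most of the transcriptome, with 7795 of 10586 tested genes called, 3426 higher in testis and 4369 higher in ovary. In ovaries bcd reached 216.5 FPKM against 1.08 FPKM in testis, prohibitin 346.0 against 28.3 FPKM, and armadillo, the beta-catenin of adhesion and Wnt signalling, 407.3 against 54.0 FPKM. Sxl was 6.74-fold and yp3 7.85-fold higher in ovary. The value of yp3 rests mostly on the CS ovary library, which stood 10.53-fold above the mean of the testis columns, and the CSaY library 2.68-fold. The cytosolic chaperonin genes CCT-eta and CCT-zeta were 2.75-fold and 2.60-fold higher in ovary, and CCT-delta did not pass the test (341.3 FPKM in ovary, 351.4 FPKM in testis). In testes GST reached 3359 FPKM, CYB1 328.1 FPKM, MdaE7 227.0 FPKM, IR25a, an ionotropic chemoreceptor, 112.3 FPKM, and SPN9 72.3 FPKM. Of the 44 tested genes with a symbol 20 were higher in testis, 15 were higher in ovary and 9 were not called. The P450 groups had 23 genes higher in testis and 2 higher in ovary of 37 tested, a called share no larger than that of the other genes (67.6% against 73.7%, Fisher's exact test, adjusted p = 0.954). HSP70 was 2.52-fold higher in ovary and hsp20 was 6.74-fold higher in testis. The median log2 ratio of testis to ovary was -0.37 over the tested genes in the pooled columns, on which the folds rest, and -0.03 in the strain columns. The largest differences belonged to LOC101890350, at 2351 FPKM in testis and listed at 0 in ovary, and LOC101889547, at 6771 FPKM in ovary and 6.44 FPKM in testis.

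Ovary levels of the strongest testis genes followed their testis levels. For 74 genes with at least 1000 FPKM in testis and below 1 FPKM in each head column, the median ovary level was 0.168% of the testis level in the CS ovary library and 0.305% in the CSaY ovary library, and 0.322% in the pooled ovary column (quartiles 0.255 to 0.374%). GST and nAChRbeta3 lay at 0.262% and 0.267% in the pooled column, within those quartiles, so their folds of 381.9 and 374.8 between testis and ovary depend on it. The ovary values of GST and nAChRbeta3 also differed 1.60-fold and 1.72-fold between the CS and CSaY libraries, in opposite directions. GST was higher in the CSaY library (6.25 FPKM in CS, 10.0 FPKM in CSaY), as the medians of the 74 genes were. The nAChRbeta3 value was lower there (0.291 FPKM in CS, 0.169 FPKM in CSaY). SPN9 lay at 0.713%, CYB1 at 0.538% and IR25a at 3.74%.

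**Figure D3:**
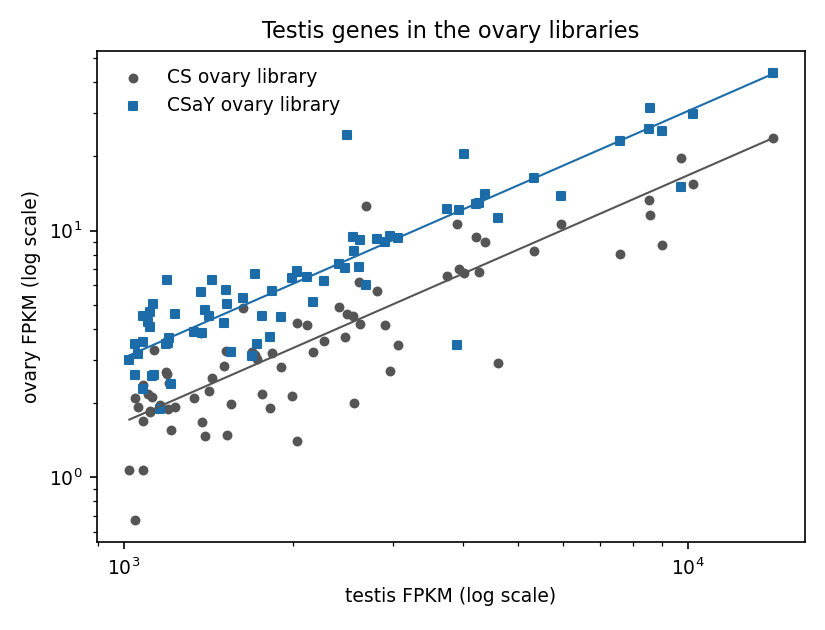
Ovary FPKM (y axis) against testis FPKM (x axis), both on log scales, for the 74 genes with at least 1000 FPKM in testis and below 1 FPKM in each head column; circles are the CS and squares the CSaY ovary library, lines mark the median ratios of 0.168% and 0.305%, and the gene listed at 0 in a library is left out there.

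Some genes that differed between the 2 kinds of males also differed between the sexes. Of the genes lower in Y^M heads 167 were higher in female than in male heads, among them diptericin, ODC and yp3, diptericin through the CS female library alone. In 133 of these 167 genes III^M heads lay below both female libraries, and in 162 Y^M heads did. A further 81 genes lower in Y^M heads were higher in male heads, SPN13 among them. III^M heads lay above both female libraries in all 81, and Y^M heads in 61. Choosing genes by both comparisons nearly fixes the counts of 162 and of all 81, so those counts are not separate evidence. Of the genes higher in Y^M heads 29 were higher in female and 6 in male heads. Independent lists would share 59.6, 12.0, 34.3 and 6.93 genes in these 4 groups, and Fisher's exact test against independent lists gave odds ratios of 4.11 and 12.1 for the first 2 groups (adjusted p = 1.29e-37 and 5.61e-46 over 40 tests). The strain and sex comparisons share the 6 male libraries, so independent lists are not what unchanged groups would give, and the excess was not tested against groups that share libraries. Unchanged groups simulated with the same sharing gave a rho of 0 (95% range -0.018 to 0.021) across genes beside the observed -0.020. With male groups of equal size a rho of 0 follows from the design, so this simulation does not test the excess of shared calls. In gonads 954 genes were called both between Y^M and III^M testes and between testis and ovary, with 966.9 from independent lists and the same limit. Of those 954 genes 368 higher in Y^M testes and 261 lower in Y^M testes were higher in testis than in ovary.

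Between the single libraries of females 73 genes were called in heads and 28 in ovaries. In female heads ODC was 3.18-fold higher in the CSaY library (47.7 against 152.0 FPKM, q = 0.0353 in the authors' deposited table). In ovaries yp3 was 3.93-fold lower in the CSaY library (108.9 against 27.7 FPKM, q = 0.0163 in the authors' deposited table). In heads yp3 stood at 346.7 FPKM in the CS and 1328 FPKM in the CSaY library (q = 0.104 in the authors' deposited table). The largest rise in the CSaY ovary library was that of LOC101894016 on chromosome III, listed at 0 in the CS library and at 484.2 FPKM in the CSaY library.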

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

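All tests named in this part were chosen after the result they examine had been seen. Some genes stood out because the strain difference had opposite directions in different groups of flies, and in no case was the difference between the groups tested, since 1 value per group gives no spread. Among genes called in both male tissues 48 had opposite strain directions in testes and heads. Among genes called in male and in female heads 21 had opposite directions. The log2 fold change of yp3 between Y^M and III^M was -3.80 in male heads and 0.86 in testes. That of ODC between CSaY and CS was -1.11 in male heads and 1.65 in female heads, where 1 library was set against 1 library. Label permutations and the removal of single libraries could not be run on group values.

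The first pattern is the excess of strain-differing genes on chromosome III in males. Reads of diverged III^M alleles could be lost in mapping, which would make chromosome III genes look higher in Y^M males, yet 40.2% of the 378 called genes in testes were lower there (95% interval 35.4 to 45.2%), and those are not explained that way. For the higher genes such a loss cannot be told apart from a difference in expression. The 170 called in testes and tested in both tissues had a median log2 fold change of 0.19 in heads against 0.78 in testes. The 118 called in heads and tested in both kept 0.34 in testes against 0.74 (ratio 0.464, interval 0.379 to 0.541), not clearly below 0.5. Choosing genes by their calls in a tissue raises the median there, so the smaller median in the other tissue does not argue against lost alleles. A few blocks of linked or duplicated genes are argued against by the excess of 14.04 percentage points over permuted scaffolds (-2.22 to 2.38). A difference of chromosome III present in both sexes stays open, since the excess of 0.0901 in testes over ovaries rests on 1 ovary library per strain, and alleles linked to the determiner on chromosome III, or effects of the determiner itself, stay as biological explanations that were not tested.

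The second pattern is the low, even level of testis genes in the ovary libraries. Among the 74 genes the upper quartile of the ovary to testis ratio was 1.53 times the lower in the CS library and 1.29 times in the CSaY library, a narrow spread that is consistent with testis reads or RNA carried into the ovary libraries. Transcription of each gene in the ovary would hardly give 1 constant ratio. Carry-over among all libraries alike is argued against: of the 205 genes with 1000 FPKM or more in testis, 15.7% (CSaY female, 95% interval 10.6 to 22.6%) to 25.6% of those not listed at 0 in a head column lay below 0.0559% of testis there, and 39.0 to 42.4% with those at 0, against 0 (interval up to 1.87%) and at most 1.46% in the ovary libraries, although a stricter bound of 20% for the lower ends, set first, was not reached without the genes at 0. Whether reads or tissue were carried over was not tested, and for GST and nAChRbeta3 the ovary level may not come from ovary cells. The nAChRbeta3 level was, however, lower in the CSaY than in the CS ovary library, opposite to the medians of the 74 genes.

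The third pattern is that sex-biased genes were lower in Y^M than in III^M heads. For the 167 female-higher genes, female RNA in the III^M head libraries would need a median share of 41.6%, and it would carry every abundant female transcript, yet 12 of the 201 genes with at least 1000 FPKM in both female libraries lay at 0.153 to 8.47% of their lower female value in III^M heads, which argues against it. For the 81 male-higher genes this explanation has no test, since they were chosen as higher in males and added female RNA would lower such genes. A strain difference shared with females would need a negative change in female heads, where the median log2 fold change of the 248 genes was 0.24 against -0.90 in males, yet 1 female library per strain leaves this open. A difference in physiology between the 2 kinds of males stays open and was not tested.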

How the results depend on the processing

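No paired analysis was possible because the values used here are 1 per group, and for the same reason no replicate was left out. The alternatives with read counts or single libraries (DESeq2, TMM, camera, fry, quantile normalization, replicate block) were not run. The ortholog-based chromosome, single-copy, strata and chromosome III settings, and q 0.01 and 2-fold for the comparison of tissues, were chosen after seeing the data.

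Of 65 alternative values for the comparisons 49 were labelled the same, 13 moved, 2 weakened and 1 reversed. For an odds ratio this label asks only for the same side of 1 and of the p threshold, not for a like size. The odds ratio of genes lower in Y^M heads and higher in male heads, 12.1, was 26.6 at 2-fold and carries that label. Testis genes numbered 756 at q 0.01, 396 at 2-fold, 537 at 2-fold with pseudocount 0.1, 393 at 2-fold after centring and 870 at a mean of 10 FPKM. Male head genes numbered 500, 307, 368 and 306 under the first 4 of these. Genes differing between heads of the sexes numbered 834 at 2-fold after centring. Each of these settings asks for more of a gene, which lowers the count. Of the male head calls 36.7% were higher in Y^M, and 28.4% were at q 0.01, 27.7% at a mean of 10 FPKM and 23.5% at 2-fold. Of the gonad calls 44.0% were testis-higher, and 31.6% were at a mean of 10 FPKM.

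The rho between testis and head strain effects (0.0660) was 0.0278 at a mean of 10 FPKM, 0.0274 without chromosome III, and -0.000401 when genes with no chromosome were left out too, a reversed sign at a size near 0. The share of genes moving the same way was 86.1% at 2-fold. The X chromosome odds ratio in testes (3.98) was 1.46 with the ortholog-based chromosome and 3.81 for single-copy orthologs, with p = 0.524 and 0.0726 by Fisher's exact test, and the cause was not tested. For chromosome III the odds ratio ranged from 2.84 to 3.51 in testes and from 2.54 to 3.18 in male heads, on the same side of the threshold each time.

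Of 217 further values, for single genes, gene groups and shares of higher calls, 199 were labelled the same and 8 moved, each a share of higher calls. Another 10 weakened, all single genes at q 0.01, among them ODC in female heads, yp3 in ovaries, SPN13 between the sexes, and bcd and CYP6A24 in testes. None reversed.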

Other observations

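Genes with several copies differed between the strains more often than single-copy genes. In testes 20.4% of the tested genes in families with many copies in house fly and Drosophila were called, and 10.2% of single-copy orthologs (Fisher's exact test, odds ratios 1.94 and 0.542 against all other genes, adjusted p = 1.18e-17 and 3.98e-23 over 30 tests). In male heads the shares were 15.9% and 6.74% (odds ratios 2.19 and 0.488). Genes without a Drosophila ortholog were called in 17.3% of cases in testes (odds ratio 1.46, Fisher's exact test, adjusted p = 0.000116), in 10.99% in male heads (adjusted p = 0.0644 by the same test) and in 0.444% in female heads. Many-copy genes were also called more often between heads of the sexes (21.2%, and 10.9% of single-copy orthologs). The odds ratios there were 1.97 and 0.582 (Fisher's exact test, adjusted p = 7.46e-18 and 5.49e-18). The order was the same between the single female libraries of heads and of ovaries. Between testis and ovary the order was the other way, with 75.7% of single-copy orthologs and 69.97% of many-copy genes called. How reads were divided among similar copies is not given in the sources used here.

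Called genes had called neighbours. In testes 65 adjacent gene pairs on chromosome III and 75 pairs on the other chromosomes were both called in the same direction, against 36.9 and 27.9 when calls were permuted among the genes of chromosome III or of the others. In male heads the numbers were 36 and 38 pairs, against 15.6 and 15.6 (p = 0.0005 for each of the 4, the smallest that 2000 permutations can give). Pairs called in opposite directions were not in excess, with 21 on chromosome III in testes against 34.6 permuted. These tests were chosen after the data had been seen.

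Genes lower in Y^M than in III^M heads were often higher in testis than in ovary. Of those lower in Y^M heads 233 were higher in testis than in ovary, where independent lists would share 116.1 (Fisher's exact test, odds ratio 3.49, adjusted p = 9.72e-34), and 75 were higher in ovary, where 198.7 would be shared. Of those higher in Y^M heads 97 were higher in testis, against 71.5 (Fisher's exact test, odds ratio 1.59, adjusted p = 0.000907). More of them, 111, were higher in ovary, against 122.3 (Fisher's exact test, odds ratio 0.835, adjusted p = 0.214). These comparisons have no library in common.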
